A study of Mus musculus with 18 samples.

How the data were processed

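The main measurement was the deposited table of gene counts for 18 libraries. The authors mapped reads to mm10, and per the submitters' processing notes bcl2fastq, DRAGEN and edgeR were used; their versions, the aligner settings and the gene annotation are not given in the sources used here. The deposited values are expected counts: estimated reads per gene that are not scaled between libraries, and 30% of the values above 0 are not whole numbers. The plan had assumed whole counts, so values were rounded to whole numbers for the same count-based test. The table held 55774 entries for 55487 gene identifiers, of which 168 occur more than once; repeats of an identifier held the same values and 1 was kept. The reads carry no molecular barcodes, so repeated copies of a molecule were counted. The authors also deposited comparison tables of log2 fold changes with p-values and adjusted p-values; per the file headers these have the column names that limma writes, and the model formula is not given in the sources used here. They were used for comparison alone.

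The main test was edgeR with quasi-likelihood dispersion, TMM factors and 1 mean per group over all 18 libraries, on the 14864 genes kept by the edgeR expression filter. Each gene had 12 residual degrees of freedom and 5.14 prior degrees of freedom, and the common biological coefficient of variation was 0.234. P-values were adjusted by Benjamini and Hochberg over all tested genes within each comparison, and 0.05 was the threshold. The labels do not say whether the 3 replicates of a group are separate animals, so p-values measure the spread between these libraries. Standard errors are those of the log2 fold change, intervals are 95%, and CPM values are means over 3 libraries with the standard deviation between them.

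Genes were grouped in 27 lists (20 of NK-cell processes, 6 of markers of other cells and 1 of sex-linked genes), of which 26 had enough tested members. The endothelium and stroma list had too few tested genes for a set test; its sum was mostly Pecam1, at 59.1 CPM in wild type and 75.1 CPM in knock-out when fresh, 135 and 58.0 when primed, and 247 and 152 after NKG2D. Lists were tested with the camera method of limma at a preset correlation of 0.01 between genes and again with a correlation estimated from the data, each adjusted over the lists of a comparison. Member counts were also adjusted over the list alone. Whether a response differed between genotypes was tested as the difference of 2 differences in the same fit.

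Genes were named by a rule. For genotype comparisons and differences of response it took Acly, the 8 largest rises and 8 largest falls past the threshold with a mean log2 CPM of at least 3 and, for genotype comparisons, with every knock-out library on 1 side of every wild-type library; the 2 risen and 2 fallen members of smallest p in each list; and a fixed set of effector, receptor and metabolic genes. For responses it took 5 and 5, and 1 and 1 per list. Predicted and unnamed genes and markers of other cells or sex were left out of the largest changes. The text prints a subset, and some genes that the rule takes are not reported here. Genes outside the rule are the haemoglobin genes, Lyz2, Car2, Cd68, H2-D1, Bnip3 in primed cells and the genes of the observations at the end, and they were chosen after their values were seen. The lists, the rule, the tests and most of the other settings tried were set before the data were examined.

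In a self-test, changes of known size were placed in simulated counts shaped on these libraries. In the fresh comparison edgeR recovered 7.94% of 63 genes changed 1.5-fold, 36.4% of 66 genes changed 2-fold and 82.8% of 64 genes changed 4-fold, and called 2 of 14192 unchanged genes. In the primed comparison it recovered 9.52% of 63, 51.5% of 66 and 69.2% of 65, with 0 of 14171 unchanged genes called (0 by limma voom and 19 by DESeq2). In the NKG2D comparison it recovered 7.69% of 65, 44.8% of 67 and 65.2% of 66, with 2 of 14189 unchanged genes called. Of the genes that DESeq2 called, 16%, 14.6% and 15% were unchanged ones. A list moved by 0.5 on the log2 scale passed the set test in each, with adjusted p of 6.31e-32, 3.86e-29 and 3.62e-28, and 0 of the 25 other lists did. The simulated genes were drawn independently of each other. The self-test therefore cannot show how often lists pass falsely when their genes vary together. Before changes were placed, each simulated gene had the same mean and dispersion in all conditions. The real common biological coefficient of variation was 0.162 in fresh, 0.316 in primed and 0.218 in NKG2D-stimulated cells. The recovery rates thus do not describe each condition by itself.

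The other settings tried were DESeq2, limma voom with sample quality weights, RLE factors, no filter on low counts, a stricter filter, the libraries of a comparison alone, replicate blocks, a minimum 2-fold change, genes with a mean log2 CPM of at least 3, an estimated correlation and leaving out each library. Sex of the library as a covariate, robust dispersion and the wider omission of primed knock-out replicate 1 were added after seeing the data.

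Whether equal replicate numbers pair the samples was checked from each library's deviation from its group. For equal numbers within a genotype 4 of 18 pairs of libraries correlated above 0.1 (median 0.0369, from -0.127 to 0.131), and for equal numbers between genotypes 2 of 27 did (median -0.0365). Of pairs with unequal numbers, 12 of 54 between genotypes and 3 of 36 within a genotype did. The 3 pairs of wild-type replicate 1 were among the 4, and the other was of knock-out replicate 2. All 4 thus joined libraries with a female pattern of sex-linked genes. Female-pattern libraries of unlike genotype correlated at -0.0184 to 0.169. The female and male patterns follow replicate number within genotype, so a shared sex cannot be told apart from a shared animal. Pairing is neither shown for all numbers nor ruled out. The numbers were not used as pairs.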

Results

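RNA was sequenced from sorted YFP-positive splenic natural killer (NK) cells of mice, in 18 libraries. Every library, of either genotype, is labelled with a tamoxifen diet of 48 hours and a time of 5 days after tamoxifen. The cells carried either the tamoxifen-inducible Cre driven from Ncr1 alone (wild type) or the same driver with floxed Acly (knock-out), the gene of ATP-citrate lyase, which makes acetyl-CoA from citrate in the cytosol. Each genotype was profiled in 3 conditions with 3 libraries per group: fresh cells, cells primed with IL-15 at 100 ng/ml for 72 hours, and primed cells that were washed and stimulated through the activating receptor NKG2D by plate-bound reagent at 20 ug/ml for 6 hours. Primed knock-out replicate 1 had the smallest total of reads and held 14695 genes with a read, where each of the other libraries held at least 17877. Xist and the Y-linked genes gave a female pattern in wild-type replicate 1 and knock-out replicate 2 of every condition and a male pattern in the rest, so that each group had 1 female-pattern library.

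Acly mRNA was lower in every knock-out library than in every wild-type library of the same condition. In fresh cells it was 250.3 ± 16.7 CPM (counts scaled to library size; SD, n = 3) in wild type and 18.9 ± 5.66 in knock-out, which left 7.6% (95% interval 5.58 to 10.3). In primed cells the level was 256 ± 26.9 against 42.8 ± 5.56 CPM, or 16.7% remaining (12.5 to 22.4). After NKG2D it was 164 ± 32.9 against 36.3 ± 7.22 CPM, or 22.2% remaining (16.6 to 29.6). The log2 fold changes were -3.72, -2.58 and -2.17, with adjusted p of 3.1e-08, 3.82e-07 and 2.63e-06. Acly lies on the minus strand of chromosome 11 from 100476353 to 100528000 (mm10). Deletion of the floxed exon itself was not measured, since values are per gene.

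**Figure D1:**
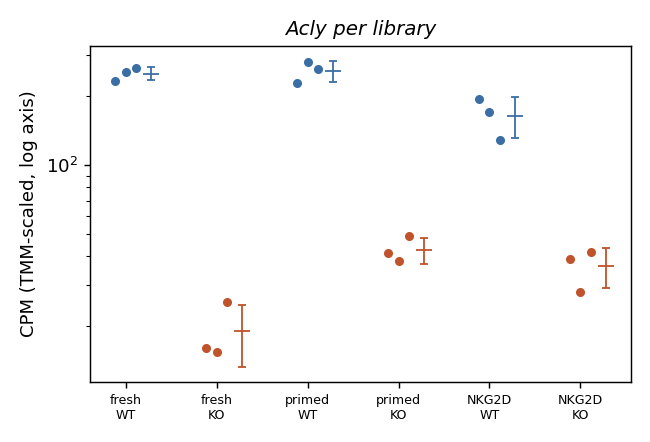
Acly in each of the 18 libraries, in CPM on a log axis, with wild type in blue and knock-out in orange. The bar beside each group of 3 points is the mean with SD; fresh knock-out libraries lie between 15.3 and 25.5 CPM and fresh wild-type libraries between 232 and 265 CPM.

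The number of genes that differed between genotypes was 10 in fresh cells, 2307 in primed cells and 2708 after NKG2D, of 14864 genes tested with edgeR at adjusted p 0.05. The fresh count rests on a spread shared with the more variable cultured cells, and other settings, given below, called many more. The authors' deposited table of fresh cells held 969 higher and 971 lower genes.

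**Figure D2:**
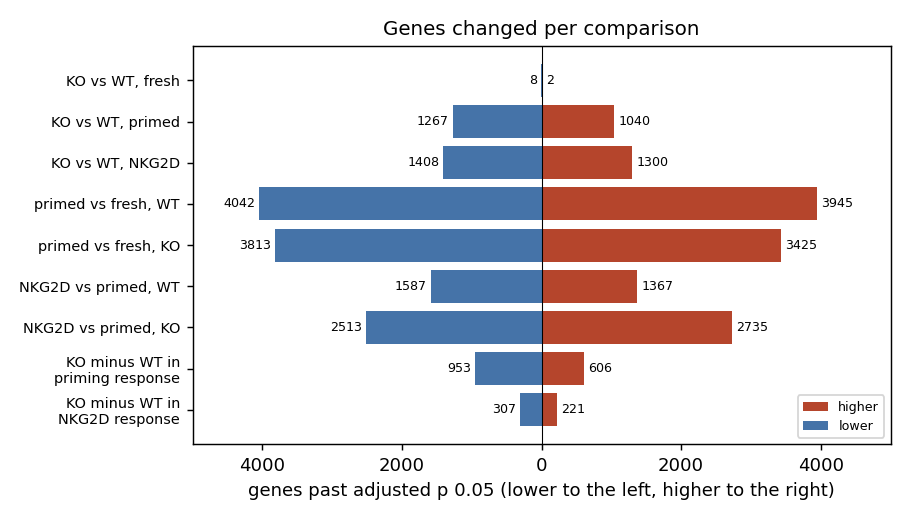
Genes past adjusted p 0.05 in each of the 9 comparisons, with genes that were higher drawn to the right and genes that were lower to the left of 0. In this fit, whose spread is shared between fresh and cultured cells, the 2 genotypes differ in 10 genes when fresh and in 2307 when primed.

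In fresh cells the comparison asks what loss of Acly changes before any culture. Few genes passed the test. Cd69, an early activation receptor that retains lymphocytes in tissue, rose by 0.92 on the log2 scale (SE 0.15, adjusted p = 0.017), from 248 ± 12.1 to 470 ± 67.9 CPM (SD, n = 3). Tsc22d3, the glucocorticoid-induced leucine zipper, rose by 0.75 (SE 0.104, adjusted p = 0.00375). Besides Acly, the genes that fell were the kinase gene Camk2b (log2 fold change -2.98, adjusted p = 0.0159), Wdfy1, which encodes an endosomal adaptor (-2.41, adjusted p = 0.00236), and the immediate-early gene Csrnp1 (-1.35, adjusted p = 0.0214). The other 4 genes that fell were the haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, red-cell transcripts whose near-identical copies share reads. The calls of Cd69, Camk2b and Csrnp1 were lost when 1 library was left out.

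The effector genes of fresh cells differed by less than the test could call. The log2 fold change was 0.06 for Ifng (adjusted p = 0.905), -0.18 for Gzmb (adjusted p = 0.789) and 0.08 for Prf1 (adjusted p = 0.909). Acss2, which makes acetyl-CoA from acetate, read 75.0 CPM in wild type and 37.5 CPM in knock-out, a difference that did not pass (SE of the log2 fold change 0.376, adjusted p = 0.272). By the camera set test 11 of 26 measured lists passed, and 2 of these held with an estimated correlation, both of other cells. The erythroid and platelet list was lower (4 of 12 measured members fell, 6 adjusted over the list alone while 1 rose; median log2 fold change -1.05; adjusted p = 3.44e-13, and 0.00876 as an adjusted p with an estimated correlation). The monocyte, macrophage and neutrophil list was lower too (median -1.61 over 11 measured members, none past the test over all genes and 4 lower adjusted over the list alone; adjusted p = 1.56e-08, and adjusted p = 0.0111 with an estimated correlation). Hbb-bs fell from 50.4 to 4.64 CPM, and Lyz2, a monocyte transcript, read 4.76 CPM in wild type and 2.56 CPM in knock-out. The sum of the erythroid list did not fall with its median, at 912 ± 145 CPM in wild type and 931 ± 72.7 in knock-out, because it is mostly Car2, a carbonic anhydrase gene, at 740 and 900 CPM.

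Small shifts in other lists of fresh knock-out cells were lost with an estimated correlation. Receptors and adaptors (median 0.19, adjusted p = 4.08e-05), oxidative phosphorylation (median 0.21, adjusted p = 4.08e-05) and ribosome biogenesis (median 0.23, adjusted p = 3.97e-05) were shifted up, each with adjusted p = 0.334 with an estimated correlation and no member past the test over all genes. Adjusted over the list alone, 1 receptor gene was higher, 5 oxidative phosphorylation genes were higher and 2 lower, and 2 ribosome biogenesis genes were higher. The histone acetyltransferase and bromodomain list was shifted down by a median of -0.19 (adjusted p = 0.00322, and adjusted p = 0.0667 with an estimated correlation), with 3 of 20 members lower when adjusted over the list alone. Calls for glycolysis (adjusted p = 0.0131), granule and death ligand genes (0.0169), the TCA cycle (0.00355) and T-cell markers (0.0371), shifted up, and for the cell cycle (0.00735), shifted down, held 0 genes past the test over all genes and were lost at adjusted p of 0.664, 0.605, 0.603, 0.632 and 0.664 with an estimated correlation. Cholesterol synthesis (median 0.07, adjusted p = 0.314) and fatty acid synthesis (median 0.10, adjusted p = 0.326) had 0 genes past the test. The count of 10 genes rests on a spread shared with cultured cells. It was 780 with the 6 fresh libraries alone, 137 with DESeq2, 1900 with limma voom and 564 with no filter on low counts, and 5 without knock-out replicate 3 or 6 without wild-type replicate 2; 1903 genes had an unadjusted p under 0.05.

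In primed cells the comparison asks how knock-out cells, with 16.7% of Acly mRNA remaining, differ once IL-15 has driven growth. Klf2, a transcription factor of lymphocyte quiescence, was 34.1 ± 6.95 CPM against 2.69 ± 0.274 in wild type (log2 fold change 3.67, SE 0.191, n = 3, adjusted p = 7.58e-09). S1pr1, the receptor for lymphocyte egress, rose by 4.43 (SE 0.461, adjusted p = 8.58e-06). Slc16a3, a lactate exporter, fell from 127 ± 28.1 to 14.0 ± 2.9 CPM (log2 fold change -3.17, SE 0.268, adjusted p = 8.59e-07).

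Glycolysis was the most uniformly lower list, with 21 of 23 measured members lower, 22 adjusted over the list alone, and a median log2 fold change of -1.33 (adjusted p = 5.01e-36, and adjusted p = 0.0155 with an estimated correlation). Pgk1, phosphoglycerate kinase, fell by 1.84 (SE 0.145, adjusted p = 4.29e-07), Aldoc, an aldolase, by 2.64 (SE 0.274, adjusted p = 8.58e-06), and the hypoxia-inducible gene Bnip3 of the same list by 2.48 (adjusted p = 6.13e-06). Pdk1, which restrains entry of pyruvate into mitochondria and stands in the acetyl-CoA supply list, fell by 1.79 (adjusted p = 0.000267). Cholesterol synthesis rose, with 16 of 24 members higher, 18 adjusted over the list alone, and a median of 0.71 (adjusted p = 2.74e-17, and adjusted p = 0.0164 with an estimated correlation). Idi1 rose by 1.72 (SE 0.134, adjusted p = 3.82e-07), and Hmgcs1, an early enzyme of the pathway, rose from 326 ± 72.1 to 875 ± 28.9 CPM (log2 fold change 1.42, adjusted p = 3e-06). Of 18 fatty acid synthesis genes, 2 rose and 1 fell, with the same counts adjusted over the list alone (median 0.10, adjusted p = 0.277). Fasn, fatty acid synthase, rose from 106 ± 5.85 to 251 ± 39.2 CPM (adjusted p = 0.000508) and the desaturase gene Scd1 fell by 1.73 (SE 0.421, adjusted p = 0.01). Acss2 had a log2 fold change of 0.74 (adjusted p = 0.208) and the citrate carrier gene Slc25a1 one of -0.38 (adjusted p = 0.265).

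**Figure D3:**
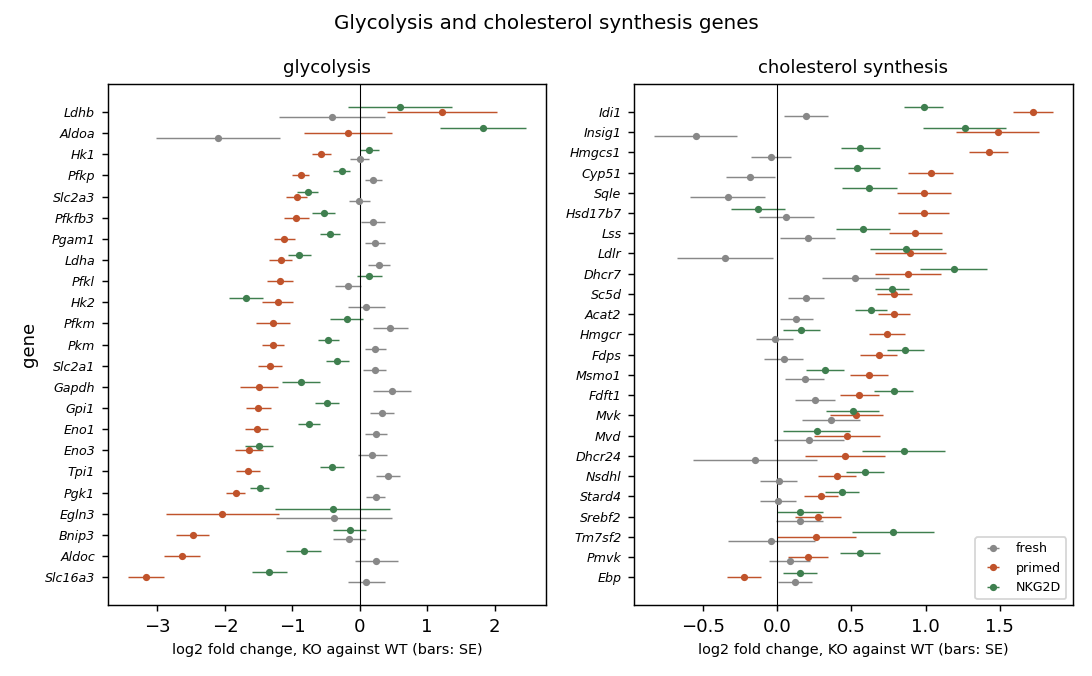
Log2 fold change of knock-out against wild type, with SE, for each measured gene of the glycolysis list (left) and the cholesterol synthesis list (right), in fresh, primed and NKG2D-stimulated cells. In primed cells 21 of 23 glycolysis genes lie significantly below 0 and 16 of 24 cholesterol synthesis genes lie significantly above 0.

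Among NK transcription factors and maturation genes of primed cells, 9 of 30 rose and 3 fell, 13 and 3 adjusted over the list alone (median 0.31, adjusted p = 2.64e-10, and adjusted p = 0.000566 with an estimated correlation). Cx3cr1, a chemokine receptor of mature NK cells, rose by 2.79 (adjusted p = 0.000174), and Nfil3, a factor of NK development, fell by 0.93 (adjusted p = 0.000238). The granule genes went both ways: 11 of 25 fell and 3 rose, with the same counts adjusted over the list alone (median -0.21, adjusted p = 0.138). Perforin, Prf1, fell by 1.06 (SE 0.194, adjusted p = 0.0014) and granzyme B, Gzmb, by 0.69 (SE 0.215, adjusted p = 0.0382). The granzyme genes Gzmc, Gzmd and Gzme, neighbours of near-identical sequence that share reads, fell by 2.49, 3.73 and 4.23. Gzmm rose by 4.56 (SE 0.285, adjusted p = 3.67e-08), as did the mast-cell-type protease gene Cma1 by 3.67. Of 36 early activation genes 10 fell and 3 rose, 12 and 3 adjusted over the list alone (median -0.14, adjusted p = 0.405). Cd69 fell by 0.87 (adjusted p = 0.000816) and Tnfrsf9, which encodes the costimulatory receptor 4-1BB, by 1.37 (adjusted p = 0.000133), while Fos rose by 2.38 (adjusted p = 6.06e-06). Ifng did not differ detectably (log2 fold change -0.15, adjusted p = 0.51). Klrk1, which encodes NKG2D, rose by 0.68 (SE 0.0933, adjusted p = 0.000119), and the natural cytotoxicity receptor gene Ncr1 by 0.64 (adjusted p = 0.00581). Other large changes were a rise of the inhibitory Fc receptor gene Fcgr2b by 2.62, and falls of the inhibitory receptor genes Ceacam1 by 3.43 and Havcr2 by 2.20 (SE 0.278, 0.528 and 0.281).

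Cell cycle genes of primed cells were shifted up (6 of 37 rose and 1 fell, also adjusted over the list alone; median 0.29; adjusted p = 0.00266), a call lost at adjusted p = 0.901 with an estimated correlation. The lists of histone deacetylases, receptors and adaptors, the TCA cycle, the integrated stress response and the erythroid and sex-linked markers did not pass, with medians and means or tests of unlike sign. Their adjusted p were 0.66, 0.964, 0.869, 0.964, 0.886 and 0.928. The B-cell, T-cell and ILC1 lists did not pass either (adjusted p of 0.594, 0.393 and 0.886). Acetyl-CoA supply (2 of 22 fell, 1 adjusted over the list alone), cytokines and chemokines (3 of 21 fell and 1 rose, also adjusted over the list alone), IL-15 and STAT5 signalling (1 rose and 1 fell of 24, none adjusted over the list alone) and histone acetyltransferases and bromodomain readers (3 of 20 rose, also adjusted over the list alone) did not pass, with adjusted p of 0.869, 0.482, 0.664 and 0.0937. Nor did oxidative phosphorylation, fatty acid oxidation, p53 and apoptosis, the interferon response or ribosome biogenesis (0.172, 0.16, 0.183, 0.424 and 0.393). The primed libraries had the widest spread between replicates, a common biological coefficient of variation of 0.316 against 0.162 in fresh cells, and wild-type replicate 3 stood apart, with H2-D1 at 4338 CPM where replicates 1 and 2 read 452 and 444. The count of 2307 became 1357 without wild-type replicate 2, 1503 without wild-type replicate 1, 1128 with primed libraries alone and 4214 with limma voom, and 841 of the genes also changed at least 2-fold.

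After NKG2D stimulation the comparison asks whether effector transcripts differ between genotypes, with 22.2% of Acly mRNA remaining in the knock-out. Effector transcripts were lower in the knock-out. Ifng, the gene of interferon gamma, was 18.8 ± 2.81 CPM against 78.5 ± 11.4 in wild type (log2 fold change -2.07, SE 0.149, n = 3, adjusted p = 3.48e-07). Gzmb was 565 ± 102 against 4406 ± 1430 CPM (-2.96, SE 0.23, adjusted p = 6.62e-07). The chemokine genes Ccl3, Ccl4 and Xcl1 fell by 2.42, 2.17 and 2.24 (SE 0.223, 0.219 and 0.182), and the cytokine genes Csf2 and Tnf fell by 3.47 and 1.47 (SE 0.497 and 0.44; adjusted p = 0.000157 and 0.027). Csf2 read 38.5 CPM in wild-type replicate 1 and 11.5 and 11.1 in the others, and its log2 fold change was -2.61 without that replicate. Klf2 and S1pr1 rose by 3.51 and 3.02.

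Of 21 measured cytokine and chemokine genes 10 fell and none rose, with 12 lower and 1 higher adjusted over the list alone (median -1.07, adjusted p = 2.85e-13, and adjusted p = 0.0137 with an estimated correlation). Of 36 early activation genes 17 fell, 19 adjusted over the list alone (median -0.67, adjusted p = 1.76e-10, and adjusted p = 0.0463 with an estimated correlation), among them Tnfrsf9 by 2.09 and Crtam, an adhesion receptor of activated lymphocytes, by 1.71. Of 25 granule and death ligand genes 14 fell and 2 rose, 15 and 2 adjusted over the list alone (median -0.46, adjusted p = 7.98e-09, and adjusted p = 0.0588 with an estimated correlation). Prf1 fell by 1.65, Gzmc by 3.62, and Gzmm and Gzmk rose by 2.69 and 1.77. Ribosome biogenesis was lower, with 23 of 29 genes down, 27 adjusted over the list alone, and a median of -0.74 (adjusted p = 2.9e-20, and adjusted p = 0.0241 with an estimated correlation). Tsr1, a ribosome maturation factor, fell by 1.29 (SE 0.134, adjusted p = 8.06e-06). Receptor genes went both ways: 12 of 37 fell and 5 rose, 14 and 7 adjusted over the list alone (median -0.20, adjusted p = 0.0195, lost at adjusted p = 0.445 with an estimated correlation). Ncr1 fell by 0.74 (adjusted p = 0.00187), whereas Klrk1 had a log2 fold change of 0.27 (adjusted p = 0.0507) and its adaptor gene Hcst one of 0.19 (adjusted p = 0.458). Other large changes were a rise of Cmah, which makes a sialic acid form, by 2.61 (SE 0.172), and falls of Il4i1, an amino acid oxidase gene, by 3.22 (SE 0.447), of the enkephalin precursor gene Penk by 3.13 (SE 0.668) and of the protease inhibitor gene Serpinb9b by 2.83 (SE 0.285).

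**Figure D4:**
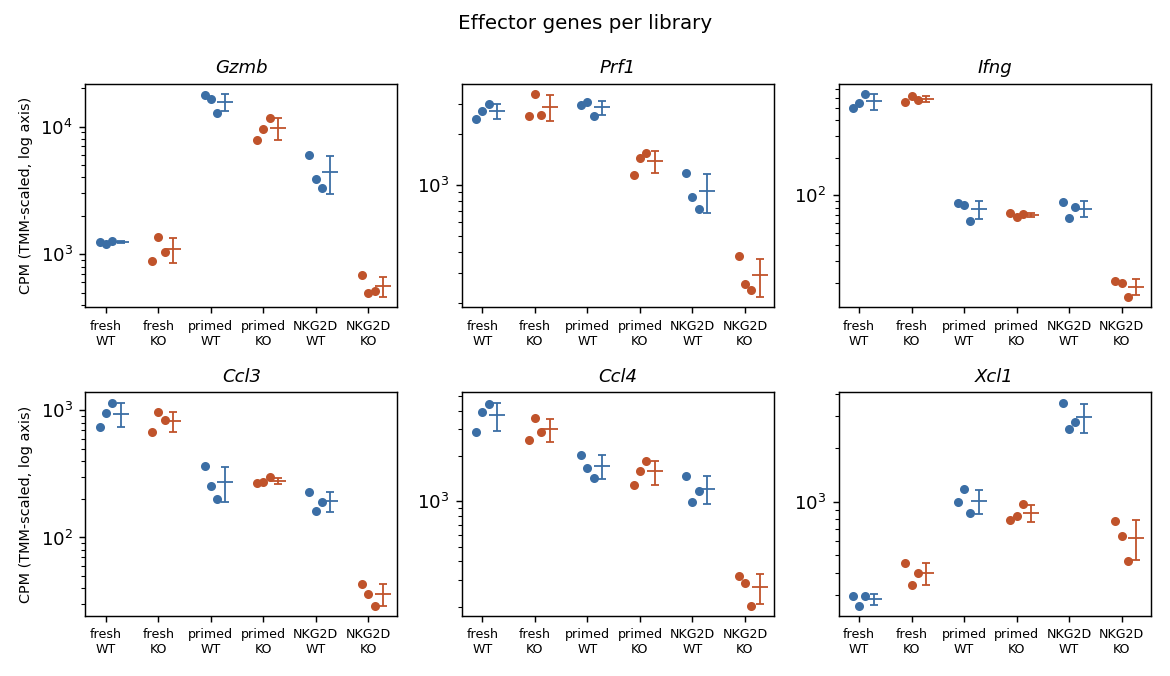
Gzmb, Prf1, Ifng, Ccl3, Ccl4 and Xcl1 in each library, in CPM on log axes, wild type in blue and knock-out in orange, with the mean and SD beside each group of 3. After NKG2D every knock-out library lies below every wild-type library for these 6 genes.

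Cholesterol synthesis stayed higher in the stimulated knock-out, with 16 of 24 genes up, 19 adjusted over the list alone, and a median of 0.59 (adjusted p = 1.76e-10, and adjusted p = 0.0463 with an estimated correlation). Idi1 and Hmgcs1 rose by 0.99 and 0.56. Acss2 rose by 1.49 (SE 0.388, adjusted p = 0.0128), from 10.1 ± 0.683 to 28.5 ± 12 CPM; Fasn had a log2 fold change of 0.56 (adjusted p = 0.0669). The histone acetyltransferase and bromodomain list rose (6 of 20, 7 adjusted over the list alone; median 0.28; adjusted p = 0.000444, and adjusted p = 0.0259 with an estimated correlation), including the bromodomain gene Brd3 by 0.83. So did NK transcription factors and maturation genes, with 12 of 30 up and 1 down, 15 and 1 adjusted over the list alone (median 0.36, adjusted p = 6.4e-07, and adjusted p = 0.00385 with an estimated correlation). Eomes, a regulator of NK maturation, rose by 0.51 (adjusted p = 0.00722).

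The other calls after NKG2D were lost with an estimated correlation. Glycolysis was lower (12 of 23, 14 adjusted over the list alone; median -0.48; adjusted p = 9.12e-09), as was oxidative phosphorylation (14 of 32, 15 adjusted over the list alone; median -0.27; adjusted p = 9.92e-06), while the cell cycle list was higher (17 of 37, 18 higher and 1 lower adjusted over the list alone; median 0.39; adjusted p = 1.44e-09) and so was the p53 and apoptosis list (6 of 23, 11 higher and 1 lower adjusted over the list alone; median 0.49; adjusted p = 0.00225). Each of these had adjusted p = 0.153 with an estimated correlation. Type I interferon genes were lower (8 of 29, also adjusted over the list alone; adjusted p = 0.000473, then adjusted p = 0.56 with an estimated correlation), as was the integrated stress response (4 of 26, also adjusted over the list alone; adjusted p = 0.00934, then adjusted p = 0.275). IL-15 and STAT5 signalling genes were shifted down (8 fell and 2 rose of 24, 10 and 3 adjusted over the list alone; adjusted p = 0.0244, then adjusted p = 0.382), with the feedback inhibitor Cish lower by a log2 fold change of -2.78, or -1.85 without wild-type replicate 1. T-cell markers were shifted down (4 fell and 1 rose of 12, 6 and 1 adjusted over the list alone; adjusted p = 0.023, then adjusted p = 0.445), while the summed list read 771 ± 30.5 CPM in wild type and 755 ± 59.7 in knock-out. Fatty acid synthesis, acetyl-CoA supply, histone deacetylases, the TCA cycle and fatty acid oxidation did not pass (adjusted p of 0.0821, 0.943, 0.37, 0.265 and 0.596), and the TCA cycle list had a median of -0.12 and a mean of 0.06. The summed monocyte list, mostly Cd68, read 73.0 ± 9.66 CPM in wild type and 114.5 ± 7.51 in knock-out. The summed erythroid list, almost all Car2, read 4133 ± 331 and 5169 ± 164 CPM. The summed B-cell list read 570.5 ± 47.2 and 600.3 ± 89.5 CPM, and the ILC1 list 373.9 ± 99.6 and 421.7 ± 30.5 CPM. The count of 2708 became 1643 without knock-out replicate 3 and 6256 with limma voom, and 748 of the genes also changed at least 2-fold.

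The knock-out effects of primed and stimulated cells overlapped. In both, 436 genes were higher where 91 would be by chance, 496 were lower where 120 would be, and 30 went in opposite directions. The log2 fold changes correlated across genes at r = 0.37 for primed and NKG2D-stimulated cells, -0.15 for fresh and stimulated cells, and 0.00083 for fresh and primed cells. Genes are not independent replicates, so no p is given. The sizes depended strongly on which low-count genes were kept, as given with the other settings below. Klf2, S1pr1 and the cholesterol genes Idi1 and Hmgcs1 were higher in both cultured conditions, and Pgk1, Gzmc, Prf1 and Wdfy1 were lower in both.

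Priming itself was compared with fresh cells in each genotype. Wild-type cells raised Gzmb by 3.65 (SE 0.238, adjusted p = 1.02e-09), from 1247 ± 33.4 to 15630 ± 2460 CPM (SD, n = 3), and Ccl1, a chemokine gene near 0 in fresh cells, to 90.2 ± 20.2 CPM. Ifng fell by 2.85 (SE 0.15, adjusted p = 6.46e-11), Klf2 by 6.67 and the maturation factor Tbx21 by 2.06. Every measured cholesterol synthesis gene rose, 24 of 24, also adjusted over the list alone (median 2.80, adjusted p = 3e-41, and adjusted p = 0.000892 with an estimated correlation), with Hmgcs1 up by 3.27 and Fdps by 4.97. The cell cycle list rose in 35 of 37 genes, also adjusted over the list alone (median 3.72, adjusted p = 1.41e-59, and adjusted p = 0.000892 with an estimated correlation). Glycolysis rose in 19 of 23 genes, 20 adjusted over the list alone (median 2.32, adjusted p = 1.34e-15, and adjusted p = 0.0654 with an estimated correlation), with Pgk1 up by 3.27. Transcription factors and maturation genes fell, 23 of 30 with 1 up, 23 and 2 adjusted over the list alone (median -1.61, adjusted p = 1.8e-16, and adjusted p = 3.4e-05 with an estimated correlation). Interferon response genes rose in 28 of 29, also adjusted over the list alone (adjusted p = 1.8e-16, then adjusted p = 0.149 with an estimated correlation), and ribosome biogenesis genes in 27 of 29 (adjusted p = 4.63e-12, then adjusted p = 0.0622). The early activation gene Fos fell by 5.52 (SE 0.27) and S1pr1 by 6.79 (SE 0.475). In all, 3945 genes rose and 4042 fell, 4509 of them at least 2-fold.

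Knock-out cells primed in the same broad way, with 3425 genes up and 3813 down, 3829 of them at least 2-fold. Gzmb rose by 3.14 (SE 0.232, adjusted p = 5.56e-09), Hmgcs1 by 4.74 and Idi1 by 6.29, Ifng fell by 3.06, Klf2 by 3.42 and Prf1 by 1.06. The residual Acly signal rose by 1.17 (SE 0.196, adjusted p = 9.37e-05). Glycolysis rose in 12 of 23 genes and fell in 4, also adjusted over the list alone (median 0.63, adjusted p = 0.0372, then adjusted p = 0.6 with an estimated correlation). Cholesterol synthesis rose in 24 of 24 genes, also adjusted over the list alone (median 3.28, adjusted p = 3.1e-64, and adjusted p = 0.000152 with an estimated correlation). Both genotypes raised 2563 genes where 909 would be expected by chance and lowered 2600 where 1040 would be, with 130 in opposite directions (r = 0.75 across genes). Most erythroid and monocyte markers of fresh cells were near 0 after priming, as with Hbb-bs and Lyz2, which read 0 CPM in every cultured group. Exceptions were Car2, of the erythroid list, at 2009 CPM in primed wild type and 1866 CPM in primed knock-out, and Cd68, of the monocyte list, at 52.5 and 38.1 CPM where fresh cells read 13.0 and 11.7.

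The test of whether genotypes primed differently called 1559 genes, 606 with a positive and 953 with a negative difference in log2 response. A negative difference is a smaller rise or a larger fall in the knock-out, or a fall where wild type did not fall. The response of Slc16a3 was lower by a log2 difference of -3.27 (SE 0.376, adjusted p = 0.000105), that of Pgk1 by -2.08 (SE 0.201, adjusted p = 1.33e-05) and that of Gzmc by -2.68 (adjusted p = 0.00236). Pgk1-rs7, a copy of Pgk1 that shares its reads, gave -2.47. Klf2 fell less in the knock-out (difference 3.25, SE 0.245, adjusted p = 2.73e-06), as did S1pr1 (4.09, adjusted p = 0.000402) and Acss2 (1.75, SE 0.542, adjusted p = 0.0484). Hmgcs1 and Fasn rose more, by 1.46 and 1.26. In the list tests 20 of 23 glycolysis genes had a negative difference, 21 adjusted over the list alone (median -1.66, adjusted p = 1.97e-31, and adjusted p = 0.0238 with an estimated correlation). Transcription factors and maturation genes had a positive difference in 9 of 30 and a negative one in 1, 10 and 4 adjusted over the list alone (adjusted p = 4.67e-07, and adjusted p = 0.00411 with an estimated correlation). Acetyltransferases and bromodomain readers had a positive one in 2 of 20, 4 adjusted over the list alone (adjusted p = 0.00135, and adjusted p = 0.0426 with an estimated correlation). For cholesterol synthesis 10 of 24 genes rose more, 12 adjusted over the list alone (adjusted p = 5.87e-09, then adjusted p = 0.104 with an estimated correlation). Cell cycle (6 of 37 positive, 7 adjusted over the list alone), p53 and apoptosis (4 of 23 positive and 1 negative, also adjusted over the list alone), oxidative phosphorylation (11 of 32 negative, 14 adjusted over the list alone) and fatty acid oxidation (5 of 21 negative, 6 adjusted over the list alone) passed at adjusted p of 8.34e-05, 0.0301, 0.00098 and 0.0301 and were lost at adjusted p of 0.537, 0.52, 0.43 and 0.166 with an estimated correlation. Prf1 (-1.14, SE 0.272, adjusted p = 0.0131) and Tnfrsf9 (-1.90, SE 0.267, adjusted p = 0.000405) had negative differences: Prf1 fell in the knock-out alone, and Tnfrsf9 rose less there. The difference in Gzmb (-0.51, adjusted p = 0.299) and Ifng (-0.21, adjusted p = 0.538) did not pass. The count of 1559 became 842 without primed wild-type replicate 2, 2453 without primed wild-type replicate 3 and 4157 with limma voom, and 718 of the genes also differed at least 2-fold.

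NKG2D-stimulated cells were compared with primed cells. The stimulated cells had also been washed and cultured further, and no group was washed without the NKG2D reagent, so the change covers all of these steps. In wild type, Xcl1 rose by 1.55 (SE 0.178, adjusted p = 7.97e-06), from 1012 ± 156 to 2973 ± 546 CPM (SD, n = 3), Ccl1 by 4.19 and Crtam by 2.63, and the transcription factor gene Bcl6 by 4.36. Igha, the immunoglobulin alpha heavy-chain gene, rose by 9.91 (SE 0.602, 95% interval 8.64 to 11.2, adjusted p = 1.3e-08) from a level of few reads, 0.0497 ± 0.0474 CPM, to 45.5 ± 10.3 CPM. Ifng showed no detectable change (log2 fold change 0.01, adjusted p = 0.964), Gzmb fell by 1.83 and Prf1 by 1.64, and Myc, a driver of growth, fell by 3.09. Cholesterol synthesis fell in 21 of 24 genes, 23 adjusted over the list alone (median -1.49, adjusted p = 2.21e-40, and adjusted p = 0.00165 with an estimated correlation). Glycolysis fell in 17 of 23 and rose in 1, 19 and 1 adjusted over the list alone (median -1.40, adjusted p = 4.52e-26, and adjusted p = 0.0469 with an estimated correlation), and ribosome biogenesis fell in 19 of 29, 23 adjusted over the list alone (median -0.62, adjusted p = 1.32e-15, and adjusted p = 0.0469 with an estimated correlation). Interferon response genes fell in 24 of 29, 25 adjusted over the list alone (adjusted p = 1.96e-17, then adjusted p = 0.192 with an estimated correlation). Tcf7, a factor of immature and memory lymphocytes, rose by 2.15 (SE 0.162). In all, 1367 genes rose and 1587 fell. The count of 2954 became 5295 with limma voom, and 1097 of the genes also changed at least 2-fold.

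In knock-out cells the same step moved 2735 genes up and 2513 down. Ifng fell by 1.90 (SE 0.148, adjusted p = 4.29e-08), Gzmb by 4.10 (SE 0.243, adjusted p = 2.27e-09), Ccl3 by 2.95 and Ccl4 by 2.55, and Xcl1 fell by 0.46 (adjusted p = 0.049). Igha rose by 8.61 and Ccl1 by 2.93. Ribosome biogenesis fell in 29 of 29 genes, also adjusted over the list alone (median -1.54, adjusted p = 3.03e-39, and adjusted p = 0.00387 with an estimated correlation), and cholesterol synthesis in 22 of 24, 23 lower and 1 higher adjusted over the list alone (median -1.68, adjusted p = 1.05e-29, and adjusted p = 0.00387 with an estimated correlation). Both genotypes raised 1034 genes where 252 would be expected by chance and lowered 1171 where 268 would be, with 21 in opposite directions (r = 0.55 across genes). The count of 5248 became 3450 with the libraries of the comparison alone, and 2302 of the genes also changed at least 2-fold.

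The test of whether the NKG2D step acted differently in the 2 genotypes called 528 genes, 221 with a positive and 307 with a negative difference in log2 response. Effector genes were among the negative ones, with differences of -1.92 for Ifng (SE 0.204, adjusted p = 0.000392), -2.28 for Gzmb (SE 0.306, adjusted p = 0.00072), -2.46 for Ccl3 (SE 0.303, adjusted p = 0.000392), -2.06 for Ccl4, -2.01 for Xcl1 and -2.78 for Csf2 (SE 0.658, adjusted p = 0.0267). The call of Csf2 ended without stimulated wild-type replicate 1 (-1.92, adjusted p = 0.0787) and without 4 other libraries in turn. Ncr1 (-1.39), Fos (-2.89) and Il4i1 (-2.92) had negative differences as well. Fos fell to a low level in both genotypes, from 15.9 to 1.78 CPM in wild type and from 82.8 to 1.21 CPM in knock-out. Its difference comes largely from the higher primed level in the knock-out. Ncr1 also started higher there, going from 358 to 200 CPM in wild type and from 560 to 120 CPM in knock-out. Of 21 cytokine and chemokine genes 7 had a negative and 1 a positive difference, also adjusted over the list alone (median -1.17, adjusted p = 1.65e-11, and adjusted p = 0.0235 with an estimated correlation). Of 29 ribosome biogenesis genes 15 had a negative difference, 27 adjusted over the list alone (median -0.86, adjusted p = 2.12e-27, and adjusted p = 0.0224 with an estimated correlation), among them Tsr1 (-1.51, SE 0.186) and Nop56 (-1.05, SE 0.14). Glycolysis had positive differences, in 8 of 23 genes, 14 adjusted over the list alone (median 0.78, adjusted p = 1.65e-11, then adjusted p = 0.238 with an estimated correlation), with Slc16a3 at 1.83 and Bnip3 at 2.33. For these 2 genes the difference was a smaller fall in the knock-out from a lower primed level. Slc16a3 went from 127 to 17.4 CPM in wild type and from 14.0 to 6.84 CPM in knock-out. Bnip3 went from 170.5 to 28.4 CPM in wild type and from 30.6 to 25.5 CPM in knock-out. Early activation genes (4 of 36 negative, 9 adjusted over the list alone; adjusted p = 2.57e-07), granule and death ligand genes (5 of 25 negative, also adjusted over the list alone; adjusted p = 0.00021) and IL-15 and STAT5 signalling genes (3 of 24 negative, 5 negative and 1 positive adjusted over the list alone; adjusted p = 0.00509) were shifted down, with adjusted p of 0.224, 0.392 and 0.392 with an estimated correlation. Klrk1 (-0.41, adjusted p = 0.0982), Prf1 (-0.59, adjusted p = 0.259) and Acss2 (0.75, adjusted p = 0.509) did not pass. The count of 528 became 242 without stimulated wild-type replicate 1, 265 without stimulated wild-type replicate 2, 203 with the libraries of the comparison alone, 1016 with DESeq2 and 2114 with limma voom, and 264 of the genes also differed at least 2-fold.

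Across all genes that rose on average with the NKG2D step, 3094 of them, the knock-out response was larger by a median log2 difference of 0.26 (camera p = 1.17e-09, and p = 0.0376 with an estimated correlation). The 2965 genes that fell on average fell further in the knock-out, by a median of -0.24 (camera p = 2.01e-15, and p = 2.11e-05 with an estimated correlation). For priming, genes that rose on average responded less in the knock-out, by a median of -0.13 (camera p = 0.00774, then p = 0.0811 with an estimated correlation), and genes that fell had a median difference of 0.07 (camera p = 0.0293, then p = 0.271).

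**Figure D5:**
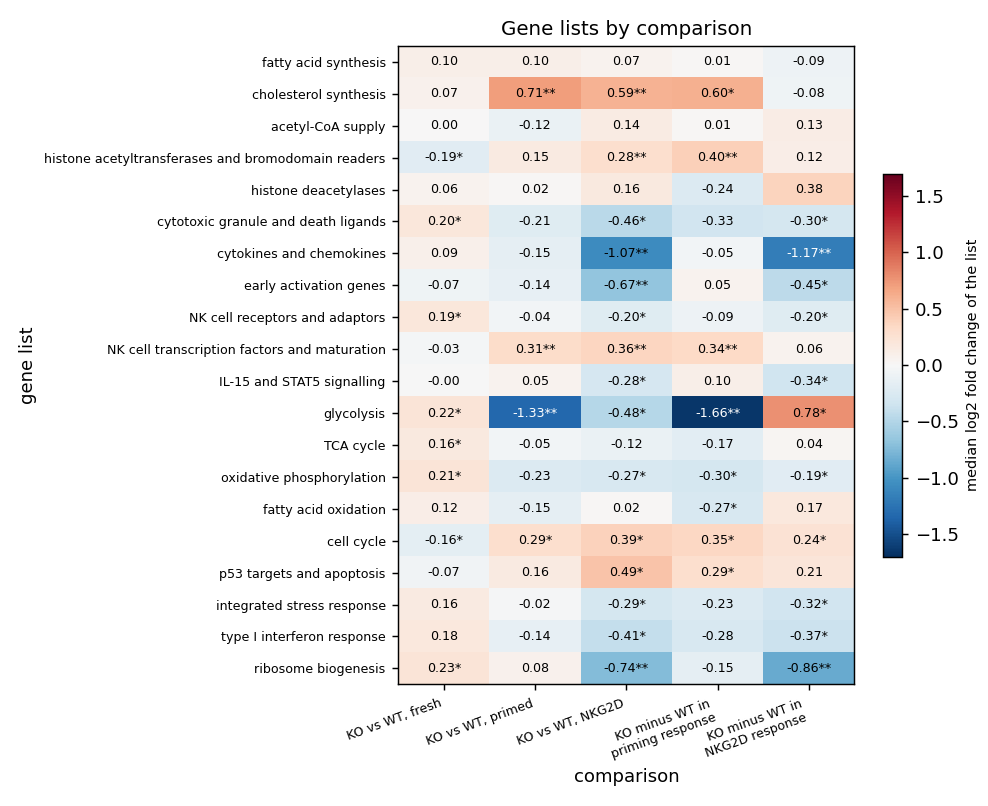
Median log2 fold change of each NK-cell gene list (each printed in its cell, red above 0 and blue below) in the 3 genotype comparisons and the 2 differences of response. A star marks adjusted p under 0.05 by the camera set test, and a pair of stars marks lists that also pass with an estimated correlation, such as glycolysis in primed cells at -1.33.

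Genes beside Acly were checked for a local effect of the engineered locus. Within 10 Mb of Acly, 0 of 259 tested genes differed in fresh cells. Only 0.0616% of other genes did there, so a count of 0 says little about a local effect. In primed cells 40 of 259 (15.4%) differed where 15.5% of other genes did (Fisher's exact test p = 1). After NKG2D 59 of 259 (22.8%) differed where 18.1% of other genes did (Fisher's exact test p = 0.0614).

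The authors' deposited table of fresh cells held 969 higher and 971 lower genes at adjusted p 0.05, that of primed cells 2443 and 1795, and that of NKG2D-stimulated cells 3137 and 3040. Over 13494 genes in both sources the log2 fold changes of the authors' deposited table correlated with those computed here at r = 0.89, 0.86 and 0.91. Of the genes called here, 100%, 92.2% and 97.9% were called in the same direction in the authors' deposited table and 0 in the opposite one.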

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

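The results here are those in which the 2 genotypes responded differently by a test of the difference itself. The counts from other splits of the samples, the comparison of the NKG2D response over all genes, the reading of Klrk1, the GC content and length test of the effector lists and the run without primed knock-out replicate 1 were chosen after the results were seen.

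The priming response differed between genotypes in 1559 genes. Of 100 drawn splits of the libraries, the real one included, 1 gave as many, and the highest other gave 795. The splits that break the genotype grouping in both conditions, 82 of them, move genotype effects into the spread between replicates, and the others carry such effects, so the splits do not decide whether chance gives this count. Among named genes the difference in log2 response was 1.137 for Acly itself, -1.141 for Prf1, 0.4941 for Klrk1, 1.745 for Acss2, 1.464 for Hmgcs1 and 1.26 for Fasn. Among lists it passed for glycolysis (adjusted p = 1.97e-31), cholesterol synthesis (5.87e-09), NK transcription factors and maturation (4.67e-07), the cell cycle (8.34e-05), oxidative phosphorylation (0.00098), histone acetyltransferases and bromodomain readers (0.00135), fatty acid oxidation (0.0301) and p53 targets and apoptosis (0.0301). As a number of lists, 8, this is reached by 10 of 100 splits, with 10 lists in the highest other, so chance is not excluded for the number of lists. With an estimated correlation 3 of the 8 held: glycolysis (adjusted p = 0.0238), NK transcription factors and maturation (0.00411) and histone acetyltransferases and bromodomain readers (0.0426).

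The NKG2D response differed in 528 genes. Of 100 drawn splits 7 gave as many, the real one included, and the highest other gave 4115. All 7 keep the real grouping, or exchange its 2 labels, in at least 1 condition, so they carry genotype effects and are no measure of chance. The split with 4115 exchanges the labels in 1 condition and adds effects that the real split subtracts, which is a structure of the samples. The 82 splits that break the grouping in both conditions gave 0 genes each, but they widen the spread as above. Chance is therefore not decided for this count either. Among named genes the difference in log2 response was -1.916 for Ifng, -2.277 for Gzmb, -2.459 for Ccl3, -2.055 for Ccl4, -2.783 for Csf2, -2.014 for Xcl1, -1.385 for Ncr1 and -0.8627 for Hmgcs1. Among lists it passed for ribosome biogenesis (adjusted p = 2.12e-27), cytokines and chemokines (1.65e-11), glycolysis (1.65e-11), early activation genes (2.57e-07), granule and death ligand genes (0.00021), IL-15 and STAT5 signalling (0.00509), the integrated stress response (0.0112), the cell cycle (0.0132), oxidative phosphorylation (0.0175), receptors and adaptors (0.0194) and the interferon response (0.0211). As a number of lists, 11, this is reached by 17 of 100 splits, with 16 in the highest other, and by 5 of the 82 that break the grouping in both conditions, so chance is not excluded for the number of lists. With an estimated correlation 2 of the 11 held: cytokines and chemokines (adjusted p = 0.0235) and ribosome biogenesis (0.0224).

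Glycolysis genes were lower in primed knock-out cells, with a median log2 fold change of -1.33. A separate set of hypoxia-inducible genes was lower too (12 of 18 fell, median -0.807; p = 0.00297 with an estimated correlation), as lower hypoxia-type transcription would require, and that test was set before its result was seen. Removing a trend with GC content and gene length left the glycolysis median at -1.34, and without primed knock-out replicate 1, the library with few genes detected, the list kept an adjusted p of 5.05e-33, so neither accounts for the pattern. What stays open is why such transcription differs, for instance cell density or oxygen in the cultures, which the labels do not give; a cause was not tested.

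Effector genes were lower in NKG2D-stimulated knock-out cells. In wild type the step raised Xcl1, from 1012 to 2973 CPM, but not Ifng (77.8 to 78.5 CPM), and Gzmb fell from 15630 to 4406 CPM. In knock-out Xcl1 went from 862 to 627 CPM, Ifng from 70.2 to 18.8 CPM and Gzmb from 9714 to 565 CPM. For Ifng and Gzmb the difference is thus a larger fall in the knock-out, while for Xcl1 a rise was missing. A weaker response to the whole step would shrink the response of all genes. The genes that rose with the step had a larger response in the knock-out, by a median of 0.263. Those genes may reflect the wash and 6 hours in culture as well as NKG2D, so a weaker response to NKG2D alone is not excluded. Less Klrk1 mRNA before stimulation is excluded, since Klrk1 was higher in primed knock-out cells by 0.683; NKG2D protein was not measured. After removal of a trend with GC content and gene length all 82 members of the cytokine, early activation and granule lists had a median of -0.693 (SE 0.187, and -0.667 before), so this trend is not the whole cause. That test was set for the members that fell, a choice that could not have come out near 0, and was changed to all members. An effect of the genotype on effector transcripts is a hypothesis, found and tested on the same data. Effects of the wash and of 6 hours in culture are not separated from those of NKG2D, and a weaker response to NKG2D stays possible.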

How the results depend on the processing

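Acly was lower past the threshold in all 3 conditions under every alternative in which its value was recorded. It was not recorded with limma voom or the stricter filter. When libraries were left out in turn, its log2 fold change ranged from -4.01 to -3.6 in fresh, -2.69 to -2.5 in primed and -2.31 to -2.04 in NKG2D-stimulated cells. The wider omission of primed knock-out replicate 1, the sex covariate and robust dispersion were chosen after seeing the data.

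The numbers of genes called moved most, and except where a setting tests fewer or more genes or libraries the cause was not tested. With limma voom they were 1900 in fresh, 4214 in primed and 6256 in NKG2D-stimulated cells, 5295 for the NKG2D step in wild type, and 4157 and 2114 for the differences of the priming and NKG2D responses. DESeq2 gave 137 in fresh cells and 1016 for the NKG2D difference. With no filter on low counts they were 564 and 887. With only the comparison's own libraries they were 780 in fresh and 1128 in primed cells, 3450 for the NKG2D step in knock-out and 203 for its difference. A minimum 2-fold change, which by construction keeps fewer genes, left 841 in primed and 748 in NKG2D-stimulated cells, 4509 and 3829 for priming in wild type and knock-out, 1097 and 2302 for the NKG2D step, and 718 and 264 for the differences. A replicate block nested in genotype gave 972 and 250 genes for the differences of priming and NKG2D responses. Within a genotype 4 of 18 pairs of libraries with equal number correlated above 0.1, 3 of them of wild-type replicate 1. All 4 joined female-pattern libraries, and 12 of 54 pairs with unequal number between genotypes also did so. Pairing is therefore neither shown for all numbers nor ruled out. With the nested block 324 of 356 values of named genes kept their side of the threshold and 32 fell short. With a replicate block across genotypes 518 of 537 kept it and 19 fell short.

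Leaving out 1 library gave 5 to 12 genes in fresh cells (5 without knock-out replicate 3, 6 without wild-type replicate 2). In primed cells it gave 1357 to 2589 (1357 and 1503 without wild-type replicates 2 and 1), and in NKG2D-stimulated cells 1643 (without knock-out replicate 3) to 3356. For the priming difference it gave 842 to 2453: 842, 940 and 2453 without primed wild-type replicates 2, 1 and 3, 911 without fresh wild-type replicate 2, and 870 and 1003 without fresh knock-out replicates 3 and 1. For the NKG2D difference it gave 242 to 598: 242 and 265 without stimulated wild-type replicates 1 and 2, 292 without stimulated knock-out replicate 3 and 307 without primed wild-type replicate 1.

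With an estimated correlation between genes, fewer lists passed: 2 in fresh and 6 in NKG2D-stimulated cells, 4 and 4 for priming in wild type and knock-out, 3 and 2 for the NKG2D step in wild type and knock-out, and 3 and 2 for the differences of the priming and NKG2D responses. With no filter 7 lists passed in primed cells, and the B-cell list, not called in fresh cells, changed direction and passed, lower in knock-out (adjusted p = 0.0162). Without 1 library the lists ranged from 7 (without primed knock-out replicate 3) to 11 for the NKG2D difference, and from 7 to 11 (without stimulated wild-type replicate 1) for the NKG2D step in wild type.

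The correlation across genes of knock-out effects in primed and NKG2D-stimulated cells was 0.549 for genes with a mean log2 CPM of at least 3, 0.118 with no filter and 0.408 with the comparisons' own libraries, and 0.285 to 0.404 without 1 library. For fresh and NKG2D-stimulated cells it was -0.35, -0.0386 with no filter, and -0.159 to -0.0746 without 1 library. For fresh and primed cells it was -0.0495 and -0.0749 to 0.0497. For genes of the average priming response the genotype difference had medians of -0.129 (rising) and 0.0717 (falling) that no longer passed with an estimated correlation (p = 0.0811 and p = 0.271). Without 1 library the rising genes ranged from -0.183 to -0.0602 and the falling genes from -0.0252, a change of direction without primed knock-out replicate 2, to 0.17.

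Values of named genes lost calls with only the comparison's own libraries, where 488 of 536 kept their side of the threshold and 44 fell short, and with no filter, where 499 of 537 kept it and 25 fell short. Of 537 values, limma voom kept the side for 509, RLE factors for 531, robust dispersion for 526 and the sex covariate for 529, with 3, 6, 11 and 7 that fell short. DESeq2 kept it for 530 of 536 and a stricter filter for 531 of 534, with 0 that fell short. The direction turned in 0 of them. Without 1 library 3746 of 4161 kept it, 396 fell short, 18 came to pass and 1 turned: the histone gene Hist1h2ap, in the NKG2D step of wild type, ranged from -5.32 to 0.0801, the last without primed wild-type replicate 3 (adjusted p = 0.97), so its call rests on that library. Leaving out 1 library also ended the calls of Cd69, Camk2b and Csrnp1 in fresh cells, Gzmb in primed cells, Tnf and Acss2 in NKG2D-stimulated cells, Acss2 and Klrk1 for the priming difference, and Csf2, Il4i1 and Hmgcs1 for the NKG2D difference. Leaving out 1 library moved some log2 values by more than 1.5-fold with the call kept: S1pr1 (3.80 to 4.99) and Ceacam1 (-5.54 to -2.95) in primed cells, Cish (-3.08 to -1.85) and Csf2 (-3.81 to -2.61) after NKG2D, and S1pr1 (3.46 to 4.68) and Gzmc (-3.47 to -2.43) for the priming difference. With 3 libraries per group 1.5-fold changes were mostly missed in the self-test.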

Other observations

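The tests of the splits of samples and of B-cell transcripts were chosen after the results were seen, as were the genes named here.

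Besides Acly, Wdfy1 and Tsc22d3 passed in the same direction in all 3 conditions. Cd69 passed in all 3 and was higher in fresh (0.92) but lower in primed (-0.87) and NKG2D-stimulated (-1.34) knock-out cells. Its call in fresh cells was lost when 1 library was left out. Wdfy1 read 71.9 against 13.5 CPM in fresh, 128 against 6.07 in primed and 128 against 17.4 in NKG2D-stimulated cells, wild type first. Tsc22d3 was higher in the knock-out, by log2 fold changes of 0.75, 0.74 and 0.80. Of 24 IL-15 and STAT5 signalling genes, 11 fell and 3 rose from primed to NKG2D-stimulated cells in wild type (adjusted p = 0.000662, then adjusted p = 0.192 with an estimated correlation) and 12 fell and 4 rose in knock-out (adjusted p = 1.02e-05, then adjusted p = 0.154 with an estimated correlation). Those that fell include Socs2 by 2.63 in wild type and 3.99 in knock-out, Pim2 by 2.76 and 3.74, and Bcl2 by 1.98 and 2.50. Those that rose include Bcl2l11, by 1.73 and 1.37.

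Igha was higher after NKG2D in both genotypes, at 45.5 CPM in wild type and 70 CPM in knock-out, and Ighm rose by 2.31 and 2.37. RNA of B cells or plasma cells is excluded as the source, since they bring abundant light-chain and joining-chain transcripts, and the higher mean of Igkc and Jchain in these groups was 0.028 CPM; this measure replaced a fold change after values were seen. A candidate explanation is TGF-beta signalling, whose targets Pmepa1 (log2 fold change 2.92 in wild type and 3.06 in knock-out), Smad7 (1.38 and 1.71) and Itgae (4.07 and 3.44) rose with it. The condition set beforehand, a set test with an estimated correlation under 0.05 in both genotypes, was not met: p = 0.0231 in wild type and p = 0.122 in knock-out. In this set 6 of 11 members rose in each genotype with 0 down. With priming the set had fallen, 7 down and 1 up in wild type, 6 down and 2 up in knock-out. In wild type Smad7 read 22.9 CPM fresh, 5.35 primed and 13.9 after NKG2D, below its fresh level, while Pmepa1 and Itgae ended above theirs. By the rule set beforehand, a p of 0.05 or more in either genotype counted against this explanation. That reading was changed after values were seen, because a missed threshold excludes nothing, and the question stays open.

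The 6 libraries of a comparison split in 10 ways, the real one included, too few for a share under 0.05. For genes, the real split and the highest other called 10 and 7 in fresh cells, 2307 and 1 in primed cells, 2708 and 0 in NKG2D-stimulated cells, 7987 and 1 for priming in wild type, 7238 and 1 in knock-out, 2954 and 280 for the NKG2D step in wild type, and 5248 and 1 in knock-out. In each of these 1 of 10 splits, the real one, gave as many. Every other split mixes both groups on each side and so moves the group effects into the spread between replicates. Low counts in the other splits therefore do not decide whether chance gives the real ones. For lists, the numbers of splits with as many were 1, 3, 1, 3, 1, 5 and 1 in the same order. The real and highest other values were 11 and 9, 4 and 5, 16 and 12, 16 and 18, 12 and 10, 7 and 10, and 13 and 11.

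Of 100 drawn splits, 2 gave a correlation as large as that of primed and NKG2D-stimulated knock-out effects (0.373), a share under 0.05. The highest other, also 0.373, was the real split with the labels of 1 condition exchanged. Splits that break the grouping in both conditions reached at most 0.285. The libraries of the 2 conditions were regrouped separately, and animals shared between conditions are not ruled out. With shared animals only 10 splits exist, too few for a share under 0.05, so chance is not decided. For fresh and NKG2D-stimulated cells 7 splits gave a correlation as large (0.152 in size, highest other 0.229). For fresh and primed cells 100 did (0.000834, highest other 0.136), so chance is not excluded for either. For the direction of the genotype difference, 1 of 100 splits was as large for genes rising with the NKG2D step (0.263, highest other 0.261). For genes falling with it 2 of 100 were (0.235, highest other 0.236). These shares are under 0.05, but the near-equal values came from splits that keep the real grouping in 1 condition. Splits that break the grouping in both conditions reached at most 0.216 and 0.164. The conditions were again regrouped separately, so chance is not decided. For genes rising with priming 3 of 100 were as large (0.129, highest other 0.148), a share under 0.05, but the shift did not pass with an estimated correlation (p = 0.0811) and 3 of 12 fits without 1 library ended its call, so it is not a firm result. For genes falling with priming 25 of 100 were as large (0.0717, highest other 0.123).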
